A study of Populus trichocarpa with 12 samples.

How the data were processed

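RNA from developing xylem of 12 trees was sequenced, 9 transgenic trees with miR397a overexpression and 3 wild-type trees. The series' design text describes the transgenic trees as separate individuals and biological replicates; their titles number them as lines. Libraries were made with an Illumina TruSeq RNA kit from CTAB-extracted total RNA, per the labels' protocols. Per the submitters' processing notes, TopHat2 2.0.3, TopHat, Bowtie and bedtools 2.14.2 were used, with no role given for each. The genome build, the annotation and the treatment of reads with several alignments are not given in the sources used here.

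The authors deposited 1 table of raw counts with 73013 rows, 1 for each transcript model of 41335 loci, and 1 column per tree. Columns were assigned to trees by the line or wild-type number in their names, and every row names a locus. The values are whole numbers that sum to different totals per library, and no normalization was found in them. Reads in stretches shared by several models of a locus were counted in each: of 14253 loci with more than 1 model, 6261 (43.9%) had identical counts for all their models in every library. Column totals therefore count many reads more than once, and a test over all rows would count such loci repeatedly. For each locus the model with the most reads over all 12 libraries was kept. This choice was made after the structure of the table was seen and before any test. The totals over loci ran from 8015226 to 34112839 reads. No pair of libraries had identical values. A read can still be counted at more than 1 locus where loci overlap or are near-identical copies. Groups of loci on chromosome 1 had the same log2 fold change, SE and mean expression to every digit given. Identical counts would give this, which points to reads counted at each of these loci. The totals over loci then count such reads more than once, and the tested loci are not all independent. How many loci are affected was not counted, and no correction was made.

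No genome or transcript sequence was used here, and the reference gene table that was used (assembly P.trichocarpa_v4.1) matched 0 of the identifiers. The files do not pair them with names, so loci are given by identifier. The chromosome is the number in the identifier; the number of loci per chromosome so obtained followed the number of genes per chromosome in the reference table (Spearman rho = 0.99 over 19 chromosomes). Lists of genes by function had been fixed before the data were examined. Because they were to be matched on gene descriptions, 4 planned results could not be run: the list tests, the laccase total, the test of predicted miR397a sites and the correlation of the laccase total with other lists. Markers of other tissues could not be examined for the same reason. The planned rule for named genes also needed descriptions. In its place, after the values were seen, 4 called loci were named: those with the smallest p and the largest fold change in each direction, or the next smallest p where both were the same locus. Other loci are described by chromosome.

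Lines and wild type were compared with edgeR 4.0.16 (R 4.3.3) as planned: loci were kept by filterByExpr (minimum count 10), scaled by TMM and tested with robust quasi-likelihood fits of a 2-group design over all 12 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Of the loci, 26298 were tested. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Log2 CPM values for correlations used a prior count of 2. Sums over loci were compared by exact permutation over the 220 splits of the trees into 9 and 3. Intervals on pooled read ratios are exact (Clopper-Pearson, 95%) and cover counting error only, as does the floor of 3 counts, since the labels' protocols name no molecular identifiers. The chromosome 3 stretch is the run of adjacent called loci on that chromosome, and was singled out after the calls were seen. The chromosome 5 stretch was defined, after the data were seen, as the longest run of neighbouring loci that each held at least 1% of the reads of some library.

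The test was checked on simulated counts drawn from the means, dispersions and library sizes of this comparison, with 26037 loci tested and 200 changed loci of at least 1 CPM. It recovered 18 of 50 loci changed 1.5-fold, 35 of 50 changed 2-fold, 50 of 50 changed 4-fold and 46 of 50 changed 8-fold, with 10 false calls among 159. At this depth and with 3 wild-type trees, simulated changes of 2-fold or less were thus often missed. The counts were drawn independently for each locus, without the variation that real libraries share. Its 159 calls also made the Benjamini-Hochberg cutoff looser than in the real comparison. Recovery there may therefore be lower.

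Alternatives planned before the data were examined were other scaling factors, other filters, DESeq2 1.42.0, limma-voom (limma 3.58.1) with and without sample quality weights, a test against a 2-fold change, and leaving out each tree in turn. Alternatives added afterwards were other choices of transcript model, leaving out the chromosome 3 or chromosome 5 stretch, the chromosome 5 share or 2 surrogate variables (sva 3.50.0) as covariates, and the 6 libraries with a low and the 6 with a high share taken apart.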

Results

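Developing xylem, the layer of young wood cells that lay down cellulose and lignin, was profiled by RNA sequencing in black cottonwood (Populus trichocarpa). The samples were 9 transgenic trees that overexpressed miR397a, a plant microRNA whose known targets are laccase mRNAs, and 3 wild-type trees of the same Nisqually-1 background. Laccases are copper enzymes of the cell wall that oxidise lignin precursors. Each transgenic tree is named below by its line number (1, 3, 5, 6, 9, 10, 17, 26 and 30). With 1 transcript model per locus, the counts summed over loci ran from 8015226 in line 5 to 34112839 in line 26 among the lines. The wild-type libraries held 13404667, 23611857 and 12580140. A read counted at several loci enters these sums each time. Rank correlations of log2 expression ran from 0.969 to 0.990 between lines, from 0.985 to 0.988 between wild-type trees and from 0.971 to 0.988 between a line and a wild-type tree. The loci carry Potri identifiers that were not paired with gene names in the sources used here, so the laccase genes were not identified among them. Chromosomes are given as the number that each identifier carries.

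The comparison of the 9 lines with the 3 wild-type trees addressed which transcripts of developing xylem differ when miR397a is overexpressed. With edgeR few loci differed, and most of those were lower in the lines, whereas DESeq2 called more loci higher than lower. A run of 6 neighbouring loci on chromosome 3 was nearly silent in 8 of the lines and at 18.4% of the wild-type level in line 17, a further 15 loci were between 1.55-fold and 7.06-fold lower, and 3 loci were higher, among them 1 that had almost no reads in wild type. Of 26298 tested loci, 24 were called (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), 21 lower and 3 higher in the lines. The values of the 9 lines and the 3 wild-type trees did not overlap at any of the 24. Chance gives this for 0.909% of unselected loci, which is no benchmark for loci called on the same difference. The median log2 fold change over all tested loci was -0.00016, a value that TMM scaling holds near 0 (0.072 with library totals). Within 0.5 of 0 on the log2 scale lay 24097 loci (91.6%). Of the 500 loci most abundant in wild type, 4 were called, all lower. The number of calls depended on the test and on single trees: DESeq2 called 131 loci (59 lower, 72 higher), among them 23 of the 24, and limma-voom with sample quality weights called 119 (72 lower, 47 higher). The edgeR count was 16 with library totals, 9 against a 2-fold change and 10 with surrogate variables as covariates, 9 of them among the 24. Leaving out line 1 raised it to 65 (54 lower, 11 higher), leaving out wild-type tree 3 lowered it to 16, and the count of higher loci was 6 without line 30 and 1 without wild-type tree 1 or wild-type tree 2.

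**Figure D1:**
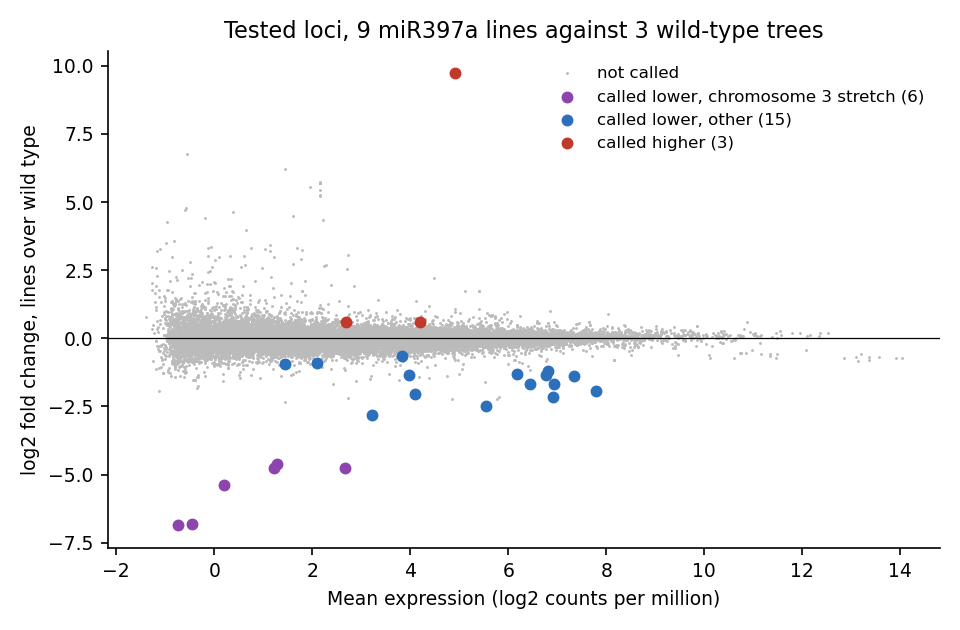
Each point is 1 of 26298 tested loci, with its mean expression in log2 CPM (read counts scaled to the size of the library) on the x axis and its log2 fold change of the 9 lines over the 3 wild-type trees on the y axis. The 24 called loci are coloured: 6 lower loci of the chromosome 3 stretch, 15 other lower loci and 3 higher loci, 1 of them at a log2 fold change of 9.72.

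The 3 higher loci were led by Potri.011G041300 on chromosome 11. It had 2 reads in the 3 wild-type libraries together and 6446 reads in the 9 lines. Its level was 39.7 ± 18.7 CPM (TMM-scaled read counts; SD, n = 9) in the lines and 0.0247 ± 0.0427 CPM (SD, n = 3) in wild type. The ratio of the pooled reads was 977, with a 95% exact interval of 270.4 to 8071 that covers counting error only. The fitted log2 fold change of Potri.011G041300 was 9.72 ± 0.84 (SE; edgeR adjusted p = 4.87e-05), a value that depends on the prior count and on 1 library. Both wild-type reads came from wild-type tree 2, and without it the fitted value was 12.4 against 0 wild-type reads (edgeR adjusted p = 0.00566). Among the lines it ranged from 23.4 CPM in line 1 to 81.7 CPM in line 10. The second locus, Potri.007G105600 on chromosome 7, rose from 13.4 ± 1.64 CPM (SD, n = 3) to 20.01 ± 1.15 CPM (SD, n = 9), a log2 fold change of 0.59 ± 0.09 (SE; edgeR adjusted p = 0.0148). The third lay on chromosome 10 and stood higher by a log2 fold change of 0.60 (edgeR adjusted p = 0.0339), a call lost in 11 of the 12 fits that each leave out 1 tree (all but that without line 1). The call of Potri.011G041300 was lost with limma-voom (adjusted p = 0.0981; over all alternatives 1.7e-16 to 0.39). That of Potri.007G105600 was lost, among others, when wild-type tree 1 or wild-type tree 2 was left out (edgeR adjusted p = 0.15 and 0.26; over all alternatives 3.36e-06 to 1).

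Outside chromosome 3, 15 loci were lower, 12 of them by at least 2-fold. Their summed level fell from 2287 ± 213 CPM (SD, n = 3) in wild type to 724 ± 109 CPM (SD, n = 9) in the lines, 3.18-fold (exact permutation test of log2 sums, two-sided, p = 0.00455, the smallest that the 220 splits of 9 and 3 trees allow). The lines spanned 531.9 CPM in line 6 to 899.8 CPM in line 1, and the wild-type trees 2143 to 2532 CPM. These loci were chosen on the same libraries, so the sum is not independent evidence of their direction. The call with the smallest p was Potri.008G073700 on chromosome 8, at 497 ± 14.8 CPM (SD, n = 3) in wild type and 129.8 ± 22.4 CPM (SD, n = 9) in the lines, a log2 fold change of -1.94 ± 0.13 (SE; edgeR adjusted p = 9.74e-06).

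Several of these 15 lower loci were direct neighbours in the order of identifiers. On chromosome 6, 3 adjacent loci fell together from a summed 694 ± 35.7 CPM in wild type to 279 ± 33.6 CPM in the lines (SD, n = 3 and n = 9), with log2 fold changes from -1.37 to -1.20. On chromosome 9, 3 adjacent loci fell from 578 ± 182 to 152 ± 42.8 CPM, with log2 fold changes from -2.14 to -1.69. Of these, 1 lost its call in 6 of the 12 fits that leave out a tree (lines 3, 10 and 17 and each wild-type tree) and another without wild-type tree 1. On chromosome 16, 2 adjacent loci fell from 209.5 ± 16.2 to 67.8 ± 12.9 CPM, and the call of 1 was lost without wild-type tree 2. A pair of separate loci on chromosome 1 had the largest fold changes of the 15: one fell from 26.3 ± 3.05 to 3.74 ± 1.30 CPM, by 2.82 on the log2 scale, and the other from 121 ± 42.3 to 21.6 ± 5.59 CPM. A single locus on chromosome 10 fell from 131 ± 10.5 to 52.4 ± 9.13 CPM. The remaining 3 were lower by less than 2-fold (edgeR adjusted p from 0.0458 to 0.0481), and their calls were lost in 9, 10 and 11 of the 12 fits that leave out a tree. In that order they lay on chromosome 2, on chromosome 17 and under an identifier with no chromosome number, at 4.12 to 19.4 CPM in wild type. The values of single loci within these runs are uncertain where neighbours are near-identical copies, since the treatment of reads with several alignments is not given in the sources used here.

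The 6 adjacent loci on chromosome 3 were expressed in all 3 wild-type trees and nearly silent in the lines except line 17. Of the 6 calls, 2 were kept whichever tree was left out. Another was lost in 10 of the 12 such fits (all but those without line 1 or line 17), 1 without line 17, and 2 without wild-type tree 3. Their summed level was 51.0 ± 19.9 CPM (SD, n = 3) in wild type and 1.599 ± 2.95 CPM (SD, n = 9) in the lines (exact permutation test of log2(CPM + 0.1), two-sided, p = 0.00455). This stretch too was singled out on the same libraries, so that p is not independent evidence. Pooled reads numbered 2239 in wild type and 271 in the lines, a 27.2-fold lower level in the lines with a 95% exact interval of 24.0 to 31.0 for counting error. The smallest p of the 6 was that of Potri.003G169800, with 97 reads in wild type and 2 in the lines, a ratio of 160.0 (95% exact interval 43.1 to 1339.6) and an edgeR adjusted p = 3.46e-05. Line 17 held 186 of the 271 reads of the stretch and stood at 9.36 CPM, while the other 8 lines held 2 to 24 reads each. Without line 17 the pooled ratio was 76.4 (95% exact interval 61.5 to 96.0) and the lines stood at 0.628 ± 0.472 CPM (SD, n = 8), values computed after the reads of line 17 were seen. Lines 10 and 30, with 2 reads each, lay under the floor of 3 counts. The nearest tested loci on either side did not pass the edgeR test (adjusted p = 0.958 and 0.316): they stood at 3.70 ± 0.56 and 16.0 ± 0.66 CPM in the lines (SD, n = 9) and at 3.55 ± 0.71 and 13.3 ± 0.79 CPM in wild type (SD, n = 3).

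**Figure D2:**
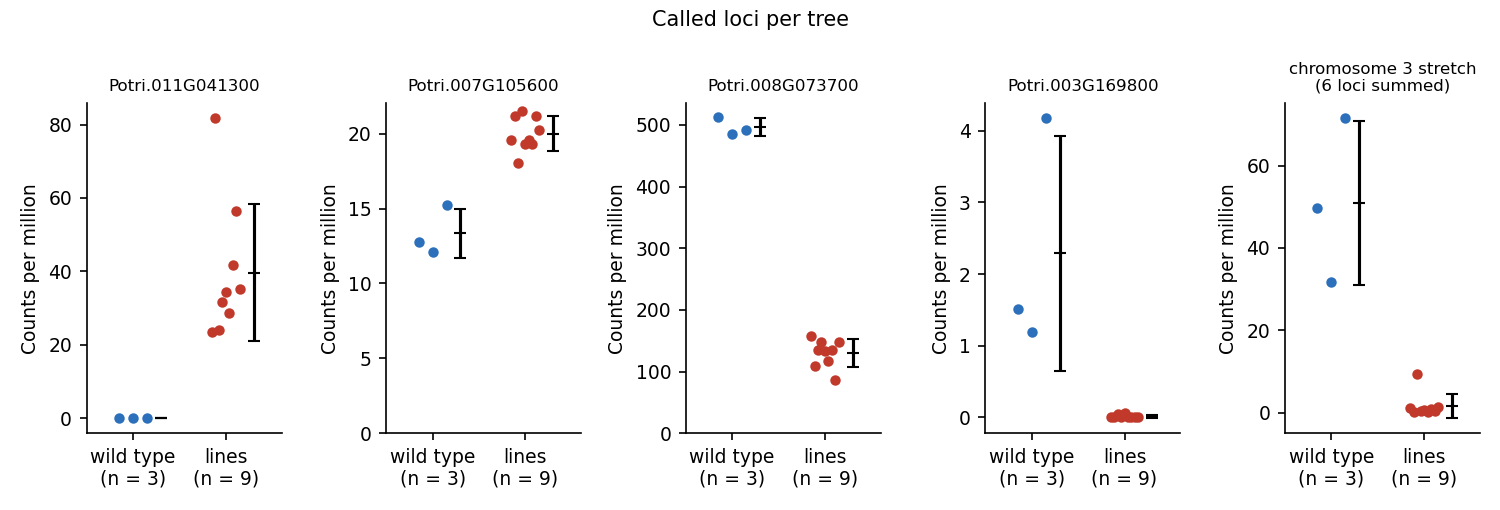
CPM (y axes, linear) of 4 called loci and of the summed chromosome 3 stretch in each wild-type tree (blue, n = 3) and each line (red, n = 9), with the mean and SD beside the points. The 9 lines lie outside the wild-type range in every panel, and line 17 stands above the other lines at the chromosome 3 stretch, at 9.36 CPM.

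A stretch of 9 neighbouring loci on chromosome 5, from Potri.005G132300 to Potri.005G133100, took very different shares of the reads in different trees. The share ran from 1.14% (line 17) to 18.7% (line 26) among the lines and was 18.9%, 2.80% and 16.0% in wild-type trees 1, 2 and 3, with exact 95% intervals at most 0.042 percentage points wide. These intervals take each count as a separate read, and whether the 9 loci share reads was not tested. The share was 7.66 ± 6.80% (SD, n = 9) in the lines and 12.6 ± 8.59% (SD, n = 3) in wild type, a difference within the spread (exact permutation test of log2 shares, two-sided, p = 0.373). With edgeR 0 of the 9 loci were called and 0 had an unadjusted p below 0.05, and the same counts came from DESeq2 and limma-voom. When the libraries were split by this share, the median log2 fold change of the 15 lower loci was -1.45 in the 6 with a low share (5 lines, 1 wild-type tree) and -1.34 in the 6 with a high share (4 lines, 2 wild-type trees). Because the groups do not overlap at these loci, their direction in each set was fixed beforehand, and only the size is measured. The edgeR test called 27 loci in the high-share set. It called 2 in the low-share set and none of the 4 named loci, but with 1 wild-type tree that set does not show whether calls depend on the share. The log2 fold changes there were 8.75 for Potri.011G041300, 0.70 for Potri.007G105600, -1.94 for Potri.008G073700 and -5.99 for Potri.003G169800. In the high-share set Potri.011G041300 and Potri.007G105600 were not called, at 12.6 and 0.56. The 12.6 was fitted against 0 wild-type reads, so its size depends on the prior count and is no measured fold.

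**Figure D3:**
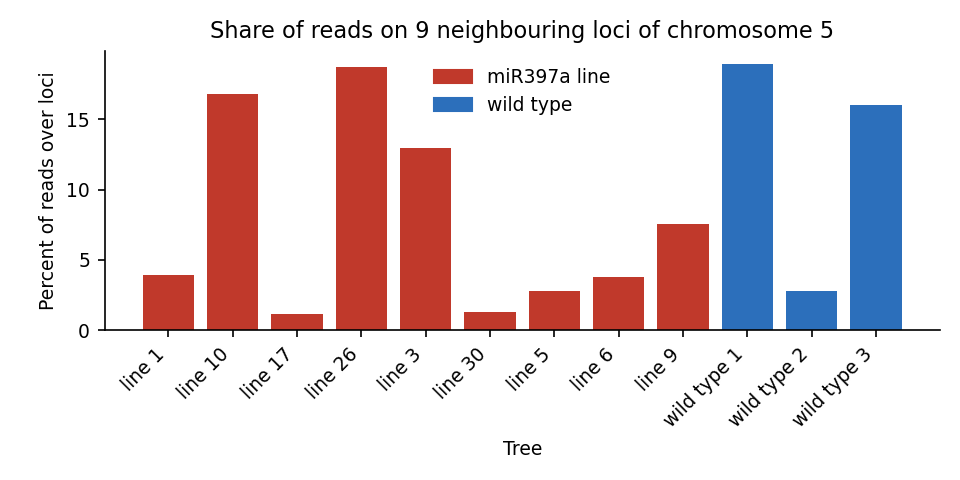
Bars give the percent of reads over loci (y axis, from 0) that fell on 9 neighbouring loci of chromosome 5 in each tree, red for the lines and blue for wild type. Lines 10, 26 and 3 and wild-type trees 1 and 3 lie between 12.99% and 18.9%, and the other trees at or below 7.55%.

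In all, 2905 loci (11.0% of those tested, the called loci included) had an unadjusted edgeR p below 0.05. Of 100 drawn splits of the 12 trees into 9 and 3, the real one included, 9 gave as many, so this number is not beyond chance. At least 8-fold fitted changes outside the chromosome 3 stretch with an unadjusted edgeR p below 0.05 were met at 24 loci that stood higher in the lines, of which only Potri.011G041300 was called, and at 0 loci that stood higher in wild type.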

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

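The alternatives chosen only after the data were seen are the other choices of transcript model, those on the chromosome 3 and chromosome 5 stretches, and the surrogate variables. Leaving out trees cannot turn the direction of a called locus, since the groups do not overlap there. The count of calls (24, of which 21 lower and 3 higher) was 23 or 24 with DESeq2 size factors, upper-quartile factors or a minimum of 1 CPM in 3 libraries, 19 with no filter, 21 with limma-voom (1 higher) and 16 with library totals (1 higher). It rose to 131 with DESeq2 (59 lower, 72 higher) and to 119 with sample quality weights (72 lower, 47 higher), and was 9 against a 2-fold change (8 lower, 1 higher). With all transcript models as rows 52 were called (44 lower, 8 higher), where models of 1 locus count apart. Without the chromosome 3 stretch 15 were called (12 lower). The 6 loci themselves drop out, and with fewer calls ranked above them the Benjamini-Hochberg adjusted p of borderline loci rises. In the main fit 3 of the other lower loci had edgeR adjusted p from 0.0458 to 0.0481. The count was 46 with the chromosome 5 share as covariate (36 lower, 10 higher), 10 with surrogate variables (9 lower, 1 higher), 2 in the 6 libraries with a low share (1 lower, 1 higher, its lone wild-type tree assumed to vary like the lines) and 27 in the 6 with a high share (26 lower, 1 higher). Leaving out 1 tree gave 16 to 65 calls, 14 to 54 lower and 1 to 11 higher. The upper ends came without line 1; the higher count was 6 without line 30 and 1 without wild-type tree 1 or 2. For these shifts the cause was not tested. Of the 24 calls, 12 were kept whichever tree was left out: 9 of the 15 other lower loci, 2 of the 6 on chromosome 3 and 1 of the 3 higher. The log2 difference of the summed chromosome 3 stretch ranged from -6.38 to -5.65. The log2 fold change ranged from 8.75 to 12.6 for Potri.011G041300 (call lost in 3 of 29, adjusted p up to 0.39), from 0.52 to 0.70 for Potri.007G105600 (lost in 7, up to 1), from -1.97 to -1.84 for Potri.008G073700 (lost in 1) and from -8.42 to -5.42 for Potri.003G169800 (lost in 1 of 28). For all 4, 1 loss is that in the low-share set, which with 1 wild-type tree says nothing of stability. For Potri.011G041300, 12.6 in the high-share set and 12.4 without wild-type tree 2 were fitted against 0 wild-type reads. These values depend on the prior count and are no measured folds. No paired analysis was possible because the numbers of the lines name transgenic lines and those of the wild type name trees. Not run for want of gene descriptions or transcripts were the alternatives for the gene list tests, the laccase total, the predicted target sites and the correlation across lines with that total; the pseudocount alternatives apply to normalized values only. Loci near the floor of 3 counts, such as the chromosome 3 stretch in the lines, have folds set by a few reads.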

Other observations

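The tests chosen only after the result was seen are the correlation across lines, the tests on the chromosome 3 stretch and both tests on neighbouring loci; the splits of the trees, the partial correlations and the random lists were set before theirs. The relation across lines was noticed in a search that also covered principal components, single loci and stretches of chromosomes. Across the 9 lines, the 15 lower loci outside chromosome 3 stood lower where Potri.011G041300 stood higher (Pearson r = -0.86, exact permutation p = 0.00271; Spearman rho = -0.93, exact permutation p = 0.00075; adjusted over 3 relations 0.00813 and 0.00225). Without lines 10 and 6, the farthest from the median, r was -0.86, and leaving out 1 line gave -0.94 to -0.83. All 15 loci had a negative r, 13 of them below -0.5. Since 8 of them lie beside another called locus and may vary together, this is not a count of independent loci. The share on the chromosome 5 stretch and the main axis of variation between the lines did not account for it as a whole. Partial r was -0.83 and -0.79 (permutation p = 0.00229 and 0.00497). The share had r = 0.46 with Potri.011G041300 across the lines, too weak to bring its partial r near 0. That partial r was thus largely fixed beforehand. Later axes of variation were not tried. The r of the 15 loci lay at percentile 0.24 of 10000 random lists matched on mean expression. The lists were not matched on the adjacency of 8 of the 15 loci, so the percentile may overstate how rare r is. The strength depends on the scaling: r was -0.85 with DESeq2 size factors and -0.56 with library totals. No p was computed for either value, so the relation is not established with library totals. The sets with a low and a high chromosome 5 share hold 5 and 4 lines, too few for a value.

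A candidate explanation for the relation, given as a hypothesis, is dose: Potri.011G041300 may report how strongly the transgene is transcribed in each line, and the 15 loci may fall with it (r = -0.86). It is consistent with the locus having 2 reads in wild type and at least 23.4 CPM in each line. What stays open is whether this locus overlaps the inserted precursor, which no sequence was at hand to test, and whether the 15 loci carry sites for miR397a; the microRNA itself was not measured in these libraries. For the chromosome 3 stretch the same test did not pass (r = -0.53, exact permutation p = 0.143; rho = -0.43, p = 0.25 by exact permutation; r = -0.32 without lines 10 and 6).

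The fall of the 6 neighbouring loci on chromosome 3 was far larger than that of the other lower loci. Loss of the stretch from the genome of line 17 is argued against by its 186 reads, 18.4% of the wild-type level, of which 182 lay on 4 of the loci with 14 to 100 reads each. The other 2 loci had 1 and 3 reads, at or under the floor of 3 counts, where the pooled wild-type shares would give 8.06 and 9.97, so loss of that part stays open, as it does for the other 8 lines, whose 2 to 24 reads could be misplaced. A tissue present only in the wild-type samples would bring its other transcripts too, but 0 further loci were at least 8-fold higher in wild type, even at an unadjusted edgeR p below 0.05 (DESeq2 0, limma-voom 1, with quality weights 0), against 24 loci, Potri.011G041300 among them, that high in the lines. The counts of 24 and 0 are not directly comparable, since a weak locus more easily lacks reads in all 3 wild-type trees than in all 9 lines. The 8-fold bound lies just above the largest fall of the other called loci, 7.06-fold, and transcripts also made in xylem need not reach it. Such a tissue is therefore not excluded. A difference between the trees that were transformed and the wild-type trees used here, unrelated to miR397a, remains possible and was not tested.

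Of the 24 called loci, 14 had a called direct neighbour, against at most 4 in 10000 random draws of as many tested loci (permutation p = 1e-04, the smallest they can give). Reads shared in full between neighbours would give every adjacent pair the same ratio in both groups. Of the 5 adjacent pairs outside chromosome 3, the log2 ratio differed between the groups in 1 (a pair on chromosome 6, by -0.17; exact permutation p = 0.00455, adjusted p = 0.0228 by Benjamini-Hochberg), which argues against full sharing for that pair. For the other 4 pairs the ratio alone does not decide. Reads counted in full at both loci would also give equal levels. In wild type the levels were 297.9 ± 14.83 and 201.4 ± 11.37 CPM on chromosome 6 (SD, n = 3). Along chromosome 9 they were 253.25 ± 83.05, 39.48 ± 9.203 and 285.6 ± 90.85 CPM. On chromosome 16 they were 181.01 ± 10.28 and 28.5 ± 5.896 CPM. These values argue against full sharing of that kind for these 4 pairs. Sharing in part stays open, as does full sharing with reads divided between loci.

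Of 100 drawn splits of the 12 trees into 9 and 3 (out of 220), 2 called at least 24 loci, the real one included. As many calls were thus rare among the drawn splits, which argues against chance for the count but does not exclude it. The other of the 2 was the split that set lines 5, 17 and 30 apart, with 1649 calls, and the next highest called 2. That split points to a structure of the samples whose source was not identified. Lines 5, 30 and 17 stood highest on the second principal component (60.1, 27.3 and 8.44, next line 10 at 5.80). The wild-type trees lay at its other end, at -33.1, -25.98 and -25.2, below the lowest line (line 1, at -7.93). The groups thus lay apart along this component, which held 16.7% of the variance. Whether miR397a or another difference between the groups lies behind this was not tested. A grouping other than lines against wild type, here of 3 lines, can therefore give far more calls than the real one. These 3 trees had low shares of reads on the chromosome 5 stretch (1.14% in line 17, 1.27% in line 30 and 2.80% in line 5), but wild-type tree 2 had the same share as line 5, and the split of lines 17 and 30 with wild-type tree 2 called 0 loci with edgeR (5787 at an unadjusted p below 0.05). With that share as a covariate the real comparison called 46 loci, 22 of them among the 24. For the 2905 loci at an unadjusted p below 0.05, 9 of the 100 splits gave as many (highest 6174, median 848), so chance is not excluded for that wider set. Each chromosome's median deviation from the mean of all trees lay between -0.03 and 0.05 on the log2 scale in every tree, where 3 copies in place of 2 would add 0.58.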
